A study of Escherichia coli with 6 samples.

How the data were processed

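The series holds 6 arrays with oligonucleotide probes for Escherichia coli K-12, 3 from a glucose-limited chemostat at 40 h and 3 at 500 h. On each array the chemostat sample was labelled with Cy5 and the batch-culture control with Cy3, and no dyes were swapped. Per the labels, slides were scanned on an Affymetrix 428 scanner, spots were quantified with Jaguar version 2.0, and ratios were formed in GeneSpring. According to the series' design text, spots with a signal below 50 were left out, the lowest ratio was set to 0.01, and ratios were normalised to the 50th percentile after background correction. The design text defines regulated genes by a ratio above 2 or below 0.5 and p at most 0.05.

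The deposited values are log10 ratios, 1 per probe and array. No label names the base. It was settled from values that recur within an array, of which 6 to 70 per array are related by small whole-number ratios with base 10 and at most 1 with base 2 or e. The medians of the log10 columns are 0.0754, 0.298 and 0.100 for 40 h replicates 1 to 3 and 0.412, 0.0538 and 0.444 for 500 h replicates 1 to 3, so the columns are not centred on 0, and why is unknown. The scale is thereby known, the centring stays unknown, and the direction is taken as sample over control from the channel labels and the term induction factor. Values below the floor of 0.01 numbered 5 on 40 h replicate 1 and 1 on 500 h replicate 2. No column belongs to a sample outside these groups (0 columns unmapped). Values per array are 1995, 3396 and 1862 at 40 h and 4523, 1934 and 4497 at 500 h, of 4608 spots.

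The ratios were read as a constant of the array times a whole-number sample signal over a whole-number control signal, and both signals were recovered by a search for that constant. With it, 34.9% to 70.7% of the values of an array are ratios of small whole numbers, against 0% to 0.107% with a slightly shifted constant. Recovered signals are in lowest terms, so a common factor of both channels is lost and each is a lower limit. The share of recovered control signals under 50, 16.3% to 42.2% of the values of an array, is therefore an upper limit. Ratios fell with the recovered control signal (Spearman correlation -0.418 to -0.753 across spots), in part by construction because that signal is their denominator, and with the brightness of both channels (-0.145 to -0.542). The loess correction and the filter on signals of at least 100 use these lowest terms. Control signals of 500 h replicates 1 and 3 were the same up to a common factor at 98.5% of 2475 spots with a recovered signal of at least 100, and those of other pairs at 0.188% to 1.49%. Labels describe these arrays as independent experiments, and whether a scan was used again is not known here.

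Gene names come from the platform annotation, in which 4087 probes have 1 gene symbol, 0 have several and 521 are not named. Symbols were updated through the gene identifiers to the reference table of assembly ASM584v2, where 4086 probes matched. That table served for names and neighbouring genes only. The 4608 spots lie in 4 by 4 blocks of 16 by 18. Names read by the IDs as deposited left the brightness of highly expressed genes and the 2 probes of a gene unrelated, so the IDs were re-read. Within each line of 4 blocks, the IDs were taken to count through block and position in transposed order. This correction was inferred from the data after they were seen, from correlations between the ends of lines of spots and the starts of other lines, and no label states it. A table of correlations of brightness between whole lines by their distance, made later, showed no clear pattern (r at most 0.0903 as deposited and 0.0450 after the correction). The correction followed a search in which 56063 other readings were scored, with single readings tried by hand not counted. They are scored again here with 1 gene set. The score was the area under the ROC curve for ribosomal protein and ATP synthase genes being brighter in the control. It was 0.465 as deposited, at most 0.690 among those other readings, at most 0.714 among 1000 random orders, and 0.967 after the correction, with a lowest value of 0.876 over single arrays and lines of blocks. For genes with 2 probes the correlation of mean log2 ratios was -0.0621 as deposited, 0.762 after the correction and at most 0.450 among random orders. For 1018 pairs of chromosomal neighbours at other positions it was 0.135 as deposited and 0.371 after the correction. These measures were in view during the search and are not independent of the choice, while differences between 40 h and 500 h played no part in it. With names as deposited the gene counts were 298 at 40 h, 2159 at 500 h and 0 for the difference, and 0 lists passed in any comparison.

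Values were turned into log2, ratios below 0.01 were set to 0.01, and the probes of a gene were averaged, which applies to 51 genes of 4036. Where the 2 probes of a gene differ, no probe was preferred. Genes with a value on at least 2 of the 3 arrays of each group compared were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 fit with both group means), and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05, two-sided. The tests of each time against the control are tests of the mean log2 ratio against 0 and leave out the spread of the control itself. Values with SD are means over arrays, and differences between times carry the standard error of the fit. Centred values come from the same fit after each array was centred on its median over its own measured genes. Those medians were 1.27 and 1.36 on 500 h replicates 1 and 3, which hold the most genes. On the other arrays they ran from 0.13 to 0.94, so centring lowers 500 h values more than 40 h values. With n = 2 at 500 h the arrays are in most cases replicates 1 and 3.

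For gene lists, cameraPR of limma was run on the moderated statistics with a preset correlation of 0.01. Lists with at least 5 measured members were tested, 32 at 500 h against the control and 31 in each other comparison. A correlation estimated from members on all 6 arrays (at least 3 needed) was used for 29 lists in each comparison. With it no list in any comparison had an adjusted p under 0.05. Negative estimates were set to 0, below the preset value. For those lists, correlation among their members did not end a call. That test also took its degrees of freedom from the 6 arrays and not from the number of genes. A call lost with it cannot be put down to the correlation alone. For the list of the RpoS general stress response at 500 h against 40 h the estimate was -0.00635. Its list test p was 0.0015 with the preset correlation and 0.0227 in that test. Members past the test were also counted when adjusted over the list alone. The design, the lists, the rule for named genes and the alternatives not listed below as added were chosen before the data were examined. That rule takes, in each comparison, the 10 highest and 10 lowest mean log2 values among genes past the test with a value of the same sign on all 3 arrays and none at the floor (211 genes qualified at 40 h, 652 at 500 h and 0 for the difference). If under 5 qualify, it takes the 10 with the smallest p as values. It adds up to 4 members of each list described and 15 genes followed in every comparison. Alternatives added after seeing the data average 500 h replicates 1 and 3, keep spots with recovered signals of at least 100, correct each array by a loess fit of the ratio on spot brightness (span 0.3), read names by the IDs as deposited, or combine the replicate block with centring.

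The gene test was tested on simulated data with the real missing values and 200 genes changed. At a log2 change of 3 it recovered 61.3% of the changed genes tested at 40 h (2109 genes in the test), 28.6% at 500 h (3965) and 35.7% for 500 h against 40 h (2101). At a log2 change of 1 it recovered 0% in each. The simulated arrays were independent, unlike the pair with a shared control. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 recovered the signals, and matplotlib 3.10.9 drew the figures. No raw scans were used here.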

Results

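Escherichia coli K-12 MG1655, a wild-type laboratory strain, was grown in mineral medium at 37 °C and compared before and during long cultivation under glucose limitation. The control was a batch culture in exponential phase (growth rate 0.63 ± 0.02 per h), sampled at an optical density of 0.4. A chemostat, a vessel fed with fresh medium at a fixed rate so that 1 nutrient limits growth, was then run at a dilution rate of 0.3 per h, and cells were taken 40 h and 500 h later. Each time point has 3 arrays, described as biological repeats. Every array compared sample RNA (Cy5) with control RNA (Cy3) and gives a log ratio per spot, positive where the chemostat sample gave the higher signal. This direction rests on the channel labels and on the authors' term induction factor. No dyes were swapped and the columns are not centred. A difference between dyes or in scale is therefore not separated from a change in transcript. Below, rose and fell describe the ratio. The 40 h arrays 1 to 3 hold values for 1995, 3396 and 1862 of 4608 spots, and the 500 h arrays hold 4523, 1934 and 4497. The number of arrays limits the precision.

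Gene names needed a correction that no label states. Read by the spot IDs as deposited, the 2 probes of genes with 2 probes did not resemble each other (r = -0.0621 across 50 genes), and genes for ribosomal proteins and ATP synthase were no brighter in the control than other genes (area under the ROC curve 0.465). After the IDs of each line of blocks were taken to run through block and position in transposed order, these values were 0.762 and 0.967. The reading was inferred from the spot signals after the data were seen and after 56063 other readings had been scored, so every gene name given here depends on it.

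**Figure D1:**
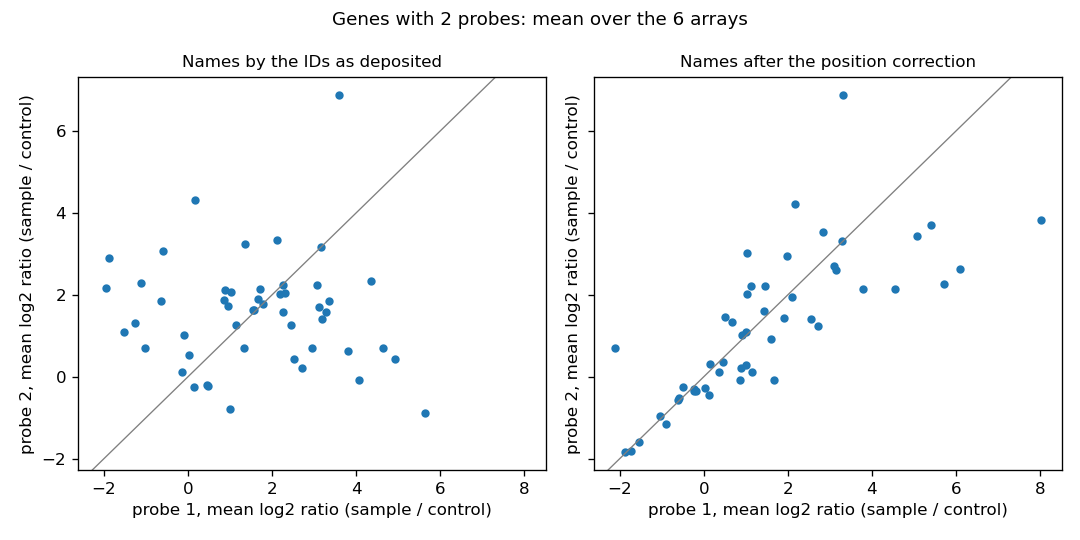
Mean log2 ratio over the 6 arrays of the 2 probes of one gene, with probe 1 on the horizontal and probe 2 on the vertical axis, and the line of equality. Each point is a gene. With names by the IDs as deposited (left) r is -0.0621, and after the position correction (right) it is 0.762.

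The first comparison asked which transcripts differed from the batch culture after 40 h. Gene lists for the uptake of maltose and other carbon sources lay higher than other genes, and those for ribosomal proteins and nucleotide synthesis lay lower, each with part of its members past the test. With an estimated correlation 0 lists passed. Of the sugar genes, malG at 5.67 ± 1.51 (SD, n = 3, centred 5.18), a membrane subunit of the maltose transporter, and malM at 4.74 ± 1.03 (SD, n = 3, centred 4.25), a periplasmic protein of the same regulon, had some of the highest log2 ratios. gatD at 4.42 ± 1.04 (SD, n = 3, centred 3.92) and gatY at 3.66 ± 0.49 (SD, n = 3, centred 3.16), which act in galactitol use, also rose. Among genes that fell were rpmH at -3.45 ± 0.76 (SD, n = 3, centred -3.95) and rplY at -3.08 ± 0.22 (SD, n = 3, centred -3.57), for ribosomal proteins L34 and L25, and purM at -3.32 ± 0.67 (SD, n = 3, centred -3.81), of purine synthesis. Of 2109 genes tested by limma, 333 changed, 220 higher and 113 lower, at an adjusted p under 0.05. The median over all tested genes was 0.52, and 0.01 after each array was centred on its own median. With centring 199 genes changed, 75 higher and 124 lower, so the split between higher and lower turned and centred values are given beside the deposited scale.

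By gene list, ribosomal protein genes shifted down against all other genes. Of the 54 measured, 0 rose and 30 fell (0 and 40 adjusted over the list alone, 0 and 25 after centring). Adjusted p was 2.43e-27, and adjusted p = 0.124 with an estimated correlation. The largest declines besides rpmH and rplY were rpsU at -2.90 ± 0.58 (SD, n = 3, centred -3.40) and rpmG at -2.68 ± 0.60 (SD, n = 3, centred -3.17). Genes of nucleotide biosynthesis, which make purines and pyrimidines, shifted down too. Of the 25 measured, 0 rose and 7 fell (0 and 10 adjusted over the list alone, 0 and 7 after centring). Adjusted p was 3.93e-08, and adjusted p = 0.0932 with an estimated correlation. Besides purM, examples are pyrD at -3.14 ± 0.56 (SD, n = 3, centred -3.63), carA at -2.94 ± 0.87 (SD, n = 3, centred -3.44) and ndk at -2.06 ± 0.78 (SD, n = 2, centred -2.69). Translation factors and aminoacyl-tRNA synthetases also lay lower than other genes. Of the 29 measured, 0 rose and 2 fell (0 and 2 adjusted over the list alone, 0 and 3 after centring). Adjusted p was 0.0175, and adjusted p = 0.361 with an estimated correlation. Both that fell were infA at -2.80 ± 0.31 (SD, n = 3, centred -3.29), initiation factor IF-1, and efp at -2.23 ± 0.17 (SD, n = 2, centred -2.85), an elongation factor. Outer membrane porins and lipoproteins were lower as a list. Of the 10 measured, 0 rose and 3 fell (0 and 3 adjusted over the list alone, 0 and 3 after centring). Adjusted p was 0.0233, and adjusted p = 0.361 with an estimated correlation. They were ompC at -1.83 ± 0.46 (SD, n = 3, centred -2.33), ompT at -1.58 ± 0.76 (SD, n = 3, centred -2.07) and ompX at -1.50 ± 0.52 (SD, n = 3, centred -1.99).

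Lists for carbon uptake lay higher than other genes at 40 h. Of the 7 measured, 3 rose and 0 fell (5 and 0 adjusted over the list alone, 3 and 0 after centring). Adjusted p was 2.34e-04, with too few members on all 6 arrays to estimate a correlation. This refers to the Mgl and maltose list, whose members past the test were malG, malM and malP at 3.59 ± 0.45 (SD, n = 2, centred 3.01). For uptake and breakdown of organic and amino acids the shift was upward. Of the 18 measured, 9 rose and 0 fell (12 and 1 adjusted over the list alone, 6 and 0 after centring). Adjusted p was 2.60e-06, and adjusted p = 0.0932 with an estimated correlation. The highest were prpC at 7.01 ± 0.42 (SD, n = 2, centred 6.42), the methylcitrate synthase of propionate use, cstA at 5.86 ± 1.35 (SD, n = 2, centred 5.28), a carbon starvation protein, dadA at 5.70 ± 1.71 (SD, n = 2, centred 5.12), a D-amino acid dehydrogenase, and acs at 5.29 ± 0.85 (SD, n = 2, centred 4.71), acetyl-CoA synthetase. The list of other sugars and polyols lay higher as well. Of the 22 measured, 9 rose and 1 fell (12 and 1 adjusted over the list alone, 6 and 1 after centring). Adjusted p was 1.33e-04, and adjusted p = 0.469 with an estimated correlation. Besides gatD and gatY, examples are melA at 3.83 ± 1.96 (SD, n = 2, centred 3.25) and gatC at 3.25 ± 0.46 (SD, n = 3, centred 2.75). Acetate use, the glyoxylate shunt and gluconeogenesis had a weaker shift upward. Of the 9 measured, 4 rose and 0 fell (6 and 0 adjusted over the list alone, 0 and 0 after centring). Adjusted p was 0.0426, and adjusted p = 0.414 with an estimated correlation. Its examples are acs, ackA at 3.64 ± 1.73 (SD, n = 3, centred 3.14), acetate kinase, maeB at 2.56 ± 1.74 (SD, n = 3, centred 2.06) and aceA at 1.49 ± 0.69 (SD, n = 3, centred 0.99). Centring ended the calls of acs (adjusted p = 0.0649), ackA (0.0633), maeB (0.0709) and aceA (0.204). After a loess correction on spot brightness, chosen after seeing the data, the lists of translation factors and of porins lost their calls at 40 h, and the other 6 kept them. Without 40 h replicate 1, 2 or 3 the lists past the test at 40 h numbered 7, 5 and 5, against 8 in the main test.

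Other genes with large ratios at 40 h were dppA at 4.12 ± 2.53 (SD, n = 3, centred 3.63), the dipeptide-binding protein, napA at 3.70 ± 2.33 (SD, n = 3, centred 3.21), a periplasmic nitrate reductase subunit, xisE at 4.11 ± 1.92 (SD, n = 3, centred 3.62), of the e14 prophage, and yebW at 4.31 ± 2.09 (SD, n = 3, centred 3.82) and ybfB at 3.64 ± 1.09 (SD, n = 3, centred 3.15). On the low side were cspF at -5.11 ± 1.09 (SD, n = 3, centred -5.60), of the cold shock protein family, ymcE at -4.03 ± 1.00 (SD, n = 3, centred -4.53), rnpA at -3.32 ± 0.83 (SD, n = 3, centred -3.81), the protein part of ribonuclease P, and dusB at -2.85 ± 0.58 (SD, n = 3, centred -3.34), a tRNA dihydrouridine synthase. Centring ended the calls of dppA (adjusted p = 0.0511) and napA (0.0629). Genes followed from the outset gave galS at 2.47 ± 1.32 (SD, n = 2, centred 1.89), malT at 1.86 ± 2.77 (SD, n = 2, centred 1.23), ptsG at 0.74 ± 0.34 (SD, n = 3, centred 0.24), aceB at 1.22 ± 0.87 (SD, n = 3, centred 0.72), rpoS at 3.09 ± 2.61 (SD, n = 2, centred 2.51), crp at -0.24 ± 0.60 (SD, n = 3, centred -0.73), ompF at 0.81 ± 1.16 (SD, n = 3, centred 0.31) and rpoB at 0.21 ± 0.58 (SD, n = 3, centred -0.28), none past the test. For mglB (4.99), lamB (8.70), malE (7.79) and fliC (5.74) a single 40 h array had a value, and no test was made.

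The 40 h counts rest on a spread pooled with the 500 h arrays. They were 0 with the 40 h arrays fitted alone and 0 without 500 h replicate 1 or 3, where limma still gave 511, 548 and 545 genes at an unadjusted p under 0.05. Without 40 h replicate 1, 2 or 3 they were 183, 131 and 201. The methods' own test gave 239 genes at the study's threshold and 2 after Benjamini-Hochberg adjustment.

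The second comparison asked the same after 500 h. Lists of ribosomal protein and acid resistance genes lay lower than other genes and that of sugar uptake higher, not all members passing, while the overall scale was shifted upward. With an estimated correlation 0 lists passed here too. rpmH at -3.84 ± 0.82 (SD, n = 3, centred -4.76), rplY at -3.69 ± 0.41 (SD, n = 3, centred -4.61) and rpsU at -3.49 ± 1.30 (SD, n = 3, centred -4.41) fell. gadX at -4.20 ± 1.15 (SD, n = 3, centred -5.12), a regulator of acid resistance, and hdeA at -3.75 ± 1.63 (SD, n = 3, centred -4.67), a periplasmic acid-stress chaperone, fell as well. malE at 4.59 ± 1.63 (SD, n = 3, centred 3.67), the maltose-binding protein, and glpK at 5.18 ± 0.36 (SD, n = 3, centred 4.26), glycerol kinase, rose. Of 3965 genes tested by limma, 2108 changed, 1818 higher and 290 lower. The median of all tested genes was 1.27, and 0.12 after centring, when 1189 genes changed, 651 higher and 538 lower. Among the 1034 genes with a value on all 6 arrays the split was opposite on the deposited scale, 73 higher and 186 lower.

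A property of the arrays bears on each 500 h count. The control signals recovered from the values of 500 h replicates 1 and 3 were the same up to a common factor at 2437 of 2475 spots (98.5%), against 0.188% to 1.49% for the other pairs of arrays, so these replicates are not independent of each other against the control. Their sample signals were the same at 0.844% of spots. With both averaged into 1 replicate, limma called 0 genes at 500 h (420 at an unadjusted p under 0.05) and 0 at 40 h (548), and with averaging and centring 13 (0 higher, 13 lower) and 36 (11 higher, 25 lower). Without 500 h replicate 1 or 3 the 500 h count was 0 as well, with 428 and 406 genes at an unadjusted p under 0.05. Of the 2108 genes, 1448 (68.7%) had no value on 500 h replicate 2, and 1417 of those were higher. The methods' own test gave 1302 genes at the study's threshold and 0 after Benjamini-Hochberg adjustment.

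Ribosomal protein genes gave the clearest list result at 500 h. Of the 54 measured, 0 rose and 51 fell (0 and 51 adjusted over the list alone, 0 and 52 after centring). Adjusted p was 3.61e-34, and adjusted p = 0.117 with an estimated correlation. Besides the 3 genes above, rplM at -2.74 ± 0.34 (SD, n = 3, centred -3.66) fell. For nucleotide biosynthesis the list lay lower. Of the 29 measured, 4 rose and 13 fell (4 and 14 adjusted over the list alone, 1 and 16 after centring). Adjusted p was 2.92e-06, and adjusted p = 0.117 with an estimated correlation. Examples are purM at -3.51 ± 0.28 (SD, n = 3, centred -4.43), carA at -3.20 ± 0.31 (SD, n = 3, centred -4.12) and pyrD at -2.92 ± 0.02 (SD, n = 2, centred -4.23), while pyrE at 8.46 ± 0.12 (SD, n = 2, centred 7.15), of pyrimidine synthesis, was higher on the pair of arrays that share a control. Translation factors and aminoacyl-tRNA synthetases lay lower as a list. Of the 32 measured, 5 rose and 8 fell (5 and 8 adjusted over the list alone, 0 and 11 after centring). Adjusted p was 2.65e-04, and adjusted p = 0.117 with an estimated correlation. Members went both ways, with infA at -2.79 ± 0.30 (SD, n = 3, centred -3.71), prfB at -1.86 ± 0.48 (SD, n = 3, centred -2.78), tyrS at 2.90 ± 0.34 (SD, n = 2, centred 1.59) and cysS at 2.35 ± 0.90 (SD, n = 2, centred 1.04). RNA polymerase, sigma factors and nucleoid proteins lay lower too. Of the 22 measured, 4 rose and 5 fell (3 and 5 adjusted over the list alone, 1 and 8 after centring). Adjusted p was 0.00517, and adjusted p = 0.117 with an estimated correlation. Examples are fis at -2.52 ± 2.21 (SD, n = 3, centred -3.44), a nucleoid protein abundant in fast growth, nusA at -2.04 ± 0.32 (SD, n = 3, centred -2.96), fliA at 4.27 ± 0.22 (SD, n = 2, centred 2.96) and stpA at 2.46 ± 1.58 (SD, n = 3, centred 1.54).

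Lists for acid resistance and for glucose uptake also lay lower at 500 h. Of the 11 measured, 0 rose and 7 fell (0 and 7 adjusted over the list alone, 0 and 7 after centring). Adjusted p was 1.08e-04, and adjusted p = 0.325 with an estimated correlation. In acid resistance, besides gadX and hdeA, gadE at -2.56 ± 0.51 (SD, n = 3, centred -3.48) and gadB at -2.54 ± 2.07 (SD, n = 3, centred -3.46) fell. For the phosphotransferase system, which takes up and phosphorylates glucose and mannose, the list was lower. Of the 7 measured, 0 rose and 3 fell (0 and 3 adjusted over the list alone, 0 and 5 after centring). Adjusted p was 7.91e-04, and adjusted p = 0.117 with an estimated correlation. They were ptsH at -2.77 ± 0.20 (SD, n = 3, centred -3.69), crr at -1.58 ± 0.58 (SD, n = 3, centred -2.50) and ptsI at -1.42 ± 0.47 (SD, n = 3, centred -2.34). Porins and lipoproteins were lower as a list. Of the 12 measured, 1 rose and 5 fell (1 and 6 adjusted over the list alone, 0 and 7 after centring). Adjusted p was 0.00154, and adjusted p = 0.117 with an estimated correlation. Examples are tolC at -1.36 ± 0.67 (SD, n = 3, centred -2.28), ompT at -1.33 ± 0.51 (SD, n = 3, centred -2.25), ompA at -1.30 ± 0.22 (SD, n = 3, centred -2.22) and ompW at 1.40 ± 0.35 (SD, n = 2, centred 0.09), and the ompW value was -0.30 after a loess correction on spot brightness. Genes of the tricarboxylic acid cycle lay lower. Of the 15 measured, 2 rose and 6 fell (2 and 6 adjusted over the list alone, 0 and 8 after centring). Adjusted p was 0.00261, and adjusted p = 0.446 with an estimated correlation. Examples are sdhC at -2.40 ± 0.82 (SD, n = 3, centred -3.32), sdhB at -2.22 ± 0.35 (SD, n = 3, centred -3.14) and sdhD at -1.80 ± 1.01 (SD, n = 3, centred -2.72), of succinate dehydrogenase, and fumC at 2.24 ± 0.18 (SD, n = 2, centred 0.93), higher, on the pair of arrays that share a control.

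The list of other sugars and polyols lay higher at 500 h, with the largest number of members called among the upward lists. Of the 59 measured, 47 rose and 1 fell (48 and 1 adjusted over the list alone, 30 and 1 after centring). Adjusted p was 3.72e-06, and adjusted p = 0.344 with an estimated correlation. The highest were xylG at 6.68 ± 1.76 (SD, n = 2, centred 5.36), uxaB at 6.53 ± 0.95 (SD, n = 2, centred 5.21), glpF at 5.63 ± 0.12 (SD, n = 2, centred 4.32) and fucI at 5.32 ± 0.64 (SD, n = 2, centred 4.01). Only 17 of the 59 had a value on 500 h replicate 2, and 14 of these were called. Among all 3965 genes tested, 1818 rose, and 651 after centring. The 1818 were 401 of the 1780 genes with a value on 500 h replicate 2 and 1417 of the rest. Genes without a value there were thus called higher more often. The share over all genes is a low yardstick for lists measured mostly on replicates 1 and 3. The list of Mgl and maltose genes lay higher as well. Of the 16 measured, 14 rose and 0 fell (14 and 0 adjusted over the list alone, 7 and 0 after centring). Adjusted p was 0.019, with too few members on all 6 arrays to estimate a correlation. Examples are mglB at 4.76 ± 0.54 (SD, n = 2, centred 3.44), malK at 4.21 ± 1.04 (SD, n = 3, centred 3.29) and malG at 3.80 ± 0.53 (SD, n = 2, centred 2.48) beside malE. Of the 16, 7 had a value on 500 h replicate 2, and 6 of these were called. For organic and amino acids the list lay higher. Of the 34 measured, 25 rose and 1 fell (27 and 1 adjusted over the list alone, 14 and 2 after centring). Adjusted p was 0.016, and adjusted p = 0.117 with an estimated correlation. Examples are prpD at 5.61 ± 0.14 (SD, n = 2, centred 4.29), aldB at 4.59 ± 0.56 (SD, n = 2, centred 3.27), acs at 4.02 ± 2.34 (SD, n = 3, centred 3.10) and tnaA at 3.90 ± 0.21 (SD, n = 2, centred 2.59). Of the 34, 13 had a value on 500 h replicate 2, and 7 of these were called. Flagella and chemotaxis genes, which build the motility apparatus, lay higher as a list. Their median was 2.64 against 1.27 for all genes, and 1.32 against 0.12 after centring. Of the 48 measured, 35 rose and 0 fell (36 and 0 adjusted over the list alone, 21 and 1 after centring). Adjusted p was 5.44e-07, with too few members on all 6 arrays to estimate a correlation. The highest were cheW at 9.20 ± 0.21 (SD, n = 2, centred 7.89), fliH at 9.02 ± 0.26 (SD, n = 2, centred 7.70), fliS at 7.05 ± 0.48 (SD, n = 2, centred 5.73) and fliL at 5.13 ± 0.03 (SD, n = 2, centred 3.82). Only 4 of the 48 had a value on 500 h replicate 2, and 1 of these rose. The call of this list thus rests mostly on the pair of arrays that share a control. For fermentation and anaerobic respiration the shift was upward on the deposited scale. Of the 35 measured, 22 rose and 0 fell (23 and 0 adjusted over the list alone, 12 and 3 after centring). Adjusted p was 0.00937, and adjusted p = 0.117 with an estimated correlation. After a loess correction on spot brightness its median was 0.03 against -0.05 for all genes, and the call was lost. Of the 8 lower lists above, those of translation, RNA polymerase, the phosphotransferase system, porins and the tricarboxylic acid cycle lost it too, and those of ribosomal proteins, nucleotides and acid resistance kept it. Examples from fermentation and anaerobic respiration are fdnG at 6.88 ± 0.07 (SD, n = 2, centred 5.56), dmsA at 5.64 ± 0.61 (SD, n = 2, centred 4.32), dmsB at 4.88 ± 0.20 (SD, n = 2, centred 3.56) and frdB at 4.86 ± 0.20 (SD, n = 2, centred 3.54), and 6 of the 35 had a value on 500 h replicate 2. With 500 h replicates 1 and 3 averaged, 10 lists passed at 500 h, 4 higher and 6 lower, against 23 in the main test. Not all of the 8 lower lists above thus kept the call.

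Other genes with large ratios at 500 h were paoC at 4.77 ± 0.33 (SD, n = 3, centred 3.85), of an aldehyde oxidoreductase, cusC at 4.75 ± 0.97 (SD, n = 3, centred 3.83), of copper efflux, hisA at 4.63 ± 2.50 (SD, n = 3, centred 3.71), of histidine synthesis, frmR at 4.56 ± 0.33 (SD, n = 3, centred 3.64), lgoR at 4.47 ± 0.97 (SD, n = 3, centred 3.55), rutC at 4.41 ± 1.45 (SD, n = 3, centred 3.49) and mhpF at 4.22 ± 1.77 (SD, n = 3, centred 3.30). On the low side were cspF at -4.68 ± 0.97 (SD, n = 3, centred -5.60), rnpA at -3.94 ± 0.21 (SD, n = 3, centred -4.86) and dusB at -3.84 ± 0.54 (SD, n = 3, centred -4.76) and secG at -3.83 ± 0.21 (SD, n = 3, centred -4.75), of the protein translocase. Centring ended the calls of hisA (adjusted p = 0.0929) and, among the list members above, of malK (0.0893), acs (0.0846), fumC (0.116), tyrS (0.0524), cysS (0.202), stpA (0.0563) and ompW (0.869). Genes followed from the outset gave galS at 3.75 ± 2.40 (SD, n = 3, centred 2.83), lamB at 2.72 ± 0.37 (SD, n = 2, centred 1.40), rpoS at 2.01 ± 0.23 (SD, n = 3, centred 1.09), aceA at 0.92 ± 0.39 (SD, n = 3, centred 0.00), ompC at -0.93 ± 0.43 (SD, n = 3, centred -1.85) and fliC at 2.63 ± 0.54 (SD, n = 2, centred 1.32), past the test on the deposited scale, and malT at 1.20 ± 0.78 (SD, n = 3, centred 0.28), ptsG at -0.74 ± 0.56 (SD, n = 3, centred -1.66), aceB at 0.92 ± 0.06 (SD, n = 3, centred -0.00), crp at 0.12 ± 0.30 (SD, n = 3, centred -0.80), ompF at 0.34 ± 0.63 (SD, n = 3, centred -0.58) and rpoB at 0.33 ± 0.85 (SD, n = 3, centred -0.59), not past it. After centring, ompC and ptsG were past the test and the other 10 were not.

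**Figure D2:**
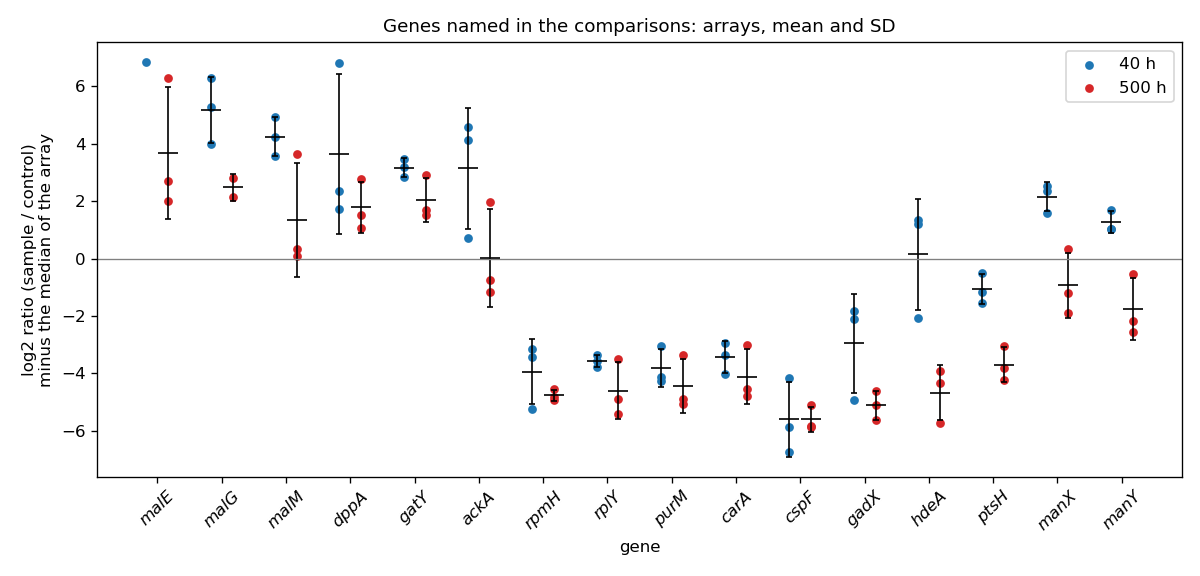
Log2 ratio of sample over control minus the median of the array, for 16 genes named in the comparisons. Points are arrays, blue for 40 h and red for 500 h, and black bars are the mean with SD. rpmH, rplY, purM, carA and cspF lie below 0 on every array, and manX and manY are above 0 on every 40 h array.

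The third comparison set 500 h against 40 h, that is long against short glucose limitation. No single gene passed the test, while 4 gene lists lay lower at 500 h with the preset correlation. With an estimated correlation 0 lists passed. Genes of the phosphotransferase system had the clearest shift, with manX at -2.66 ± 0.44 (SE, n = 6, centred -3.08), manY at -2.59 ± 0.54 (SE, n = 6, centred -3.02) and ptsH at -2.20 ± 0.41 (SE, n = 6, centred -2.62) for the difference in log2, and ptsG at -1.47 ± 0.48 (SE, n = 6, centred -1.90), the glucose transporter, at an adjusted p of 0.39. Against the control, manX (2.65), manY (1.76) and manZ (3.41) were past the test and higher at 40 h, after centring only manX. At 500 h the members past the test were ptsH, crr and ptsI, lower than the control, and not the man genes. Acid resistance genes were lower, with hdeA at -4.39 ± 1.06 (SE, n = 6, centred -4.82) and hdeB at -2.61 ± 0.88 (SE, n = 5, centred -3.43). Against the control at 40 h, 2 of the 10 measured genes of this list were already lower and 0 higher. They were gadX (-2.46) and gadW (-2.35), after centring only gadX. The list itself had no call at 40 h (list test adjusted p = 0.278). The median of this list relative to the array was -2.71 on 40 h replicate 2, near the 500 h arrays (-3.34, -3.14 and -3.71), and 0.67 and 0.34 on the other 40 h arrays. Among genes of the general stress response under the sigma factor RpoS, elaB at -2.81 ± 0.59 (SE, n = 6, centred -3.24) and wrbA at -2.56 ± 0.65 (SE, n = 6, centred -2.99) had the largest differences, and among tricarboxylic acid cycle genes sdhD at -1.73 ± 0.85 (SE, n = 6, centred -2.15) and mdh at -1.47 ± 0.66 (SE, n = 6, centred -1.90).

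For 500 h against 40 h, limma called 0 of 2101 genes, with 238 at an unadjusted p under 0.05. The methods' own test gave 178 genes at the study's threshold and 0 after Benjamini-Hochberg adjustment. On all 6 arrays 1034 genes had a value, and for 254 of them (24.6%) the groups did not overlap. A chance share of 10% holds for independent arrays only, and the control shared by 500 h replicates 1 and 3 puts it higher. The median difference of all genes was -0.16, and -0.64 after centring. Each array was centred over its own genes, which lowers the difference of every gene with 6 values by the same amount. Centred differences carry this downward offset. Of the 7 measured, 0 rose and 0 fell (0 and 5 adjusted over the list alone, 0 and 0 after centring). Adjusted p was 4.01e-07, and adjusted p = 0.202 with an estimated correlation. Of the 10 measured, 0 rose and 0 fell (0 and 1 adjusted over the list alone, 0 and 0 after centring). Adjusted p was 0.00296, and adjusted p = 0.691 with an estimated correlation. The former counts belong to the phosphotransferase list and the latter to acid resistance. For the RpoS list, 30 genes were measured and 0 passed the test, also 0 adjusted over the list alone, with adjusted p = 0.0155, and adjusted p = 0.328 with an estimated correlation. For the tricarboxylic acid cycle, 14 were measured and 0 passed, also 0 adjusted over the list alone, with adjusted p = 0.0244, and adjusted p = 0.805 with an estimated correlation. The RpoS list lost its call without 40 h replicate 2 or 3 (adjusted p = 0.0957 and 0.0934), acid resistance without 40 h replicate 1 or 3 (0.116 and 0.100), and the tricarboxylic acid cycle without 40 h replicate 2 (0.724), 500 h replicate 2 (0.129) or 500 h replicate 3 (0.0622). After loess the tricarboxylic acid cycle lost it as well (0.140), and the other 3 kept it.

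The other differences with the smallest p, all with an adjusted p of 0.357, were prpC at -3.78 ± 0.51 (SE, n = 5, centred -4.12), yeaQ at -2.39 ± 0.43 (SE, n = 6, centred -2.82), rffH at 2.60 ± 0.48 (SE, n = 6, centred 2.17), ybhP at -3.76 ± 0.57 (SE, n = 4, centred -4.49), asd at -2.67 ± 0.52 (SE, n = 6, centred -3.10) and aaeX at 3.59 ± 0.60 (SE, n = 4, centred 2.86). Genes followed from the outset differed by galS at 1.28 ± 1.45 (SE, n = 5, centred 0.94), malT at -0.66 ± 1.22 (SE, n = 5, centred -0.95), acs at -1.27 ± 1.37 (SE, n = 5, centred -1.61), aceA at -0.56 ± 0.52 (SE, n = 6, centred -0.99), aceB at -0.30 ± 0.54 (SE, n = 6, centred -0.72), rpoS at -1.08 ± 1.09 (SE, n = 5, centred -1.42), crp at 0.36 ± 0.48 (SE, n = 6, centred -0.07), ompF at -0.46 ± 0.70 (SE, n = 6, centred -0.89), ompC at 0.91 ± 0.47 (SE, n = 6, centred 0.48) and rpoB at 0.12 ± 0.60 (SE, n = 6, centred -0.31), none past the test.

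**Figure D3:**
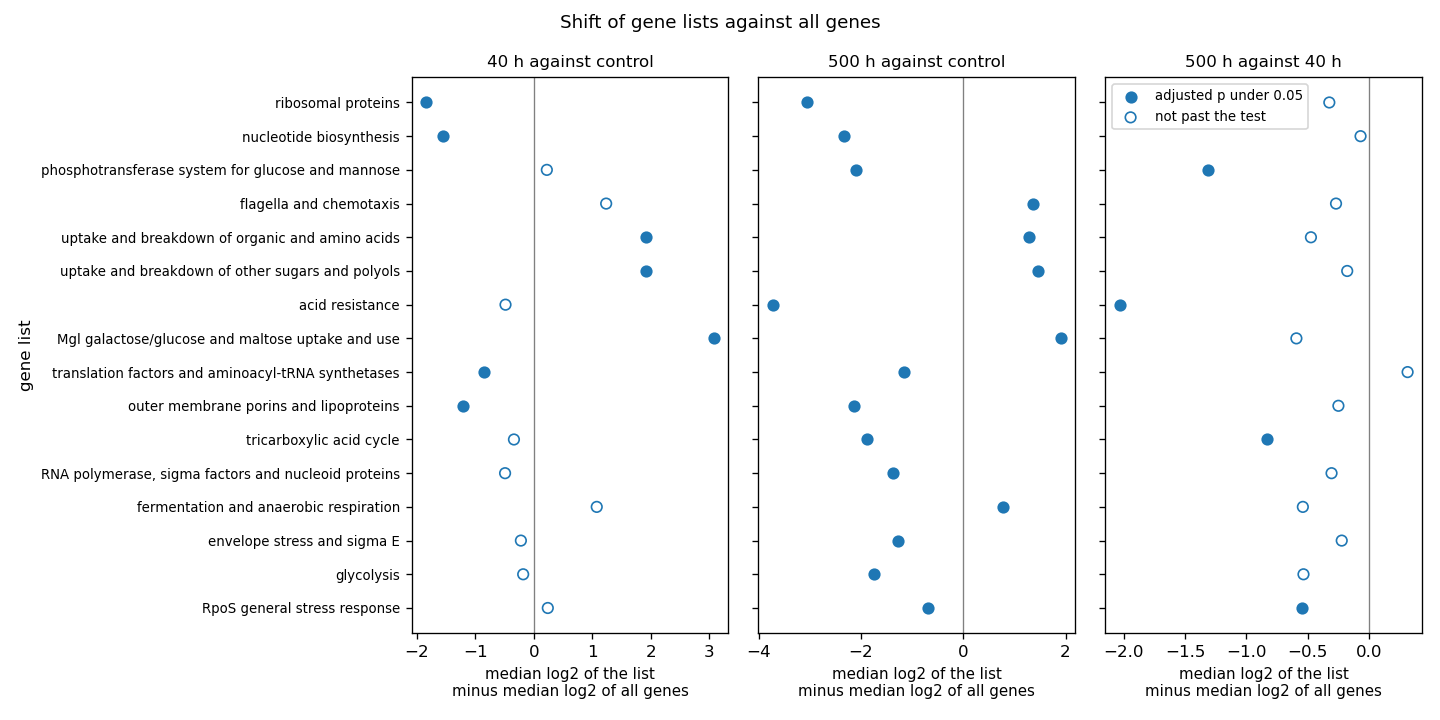
Median log2 of gene lists minus the median of all genes in the 3 comparisons, on the deposited scale. Only the lists with the smallest adjusted p in any comparison are shown, not all lists tested. Each circle is a list, filled where the list test gave an adjusted p under 0.05. Ribosomal proteins lie lowest at 40 h, acid resistance lies lowest at 500 h and in the difference.

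Across genes, changes at 40 h and at 500 h resembled each other. Over 2101 genes the mean log2 ratios correlated with r = 0.662 and a covariance of 1.30, genes not being independent replicates. In 50 simulations of unchanged groups in which only 500 h replicates 1 and 3 shared control noise, mean r was -0.00472 and the covariance -0.00296. With as much noise added that is common to the control of all 6 arrays, an assumption, they were 0.507 and 0.624. At both times 134 genes were higher and 98 lower, against at most 0 in either direction in the former simulations and at most 6 in the latter. Independent lists of these sizes share 47.0 and 15.3 genes. After centring 28 genes were higher and 115 lower at both times, where independent lists share 3.21 and 29.0. The simulations leave out real effects and the independent lists leave out the control, so the excess over either is not read as a shared effect.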

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

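The tests with the loess correction and those of the shared control on RpoS and phosphotransferase genes were chosen only after their results had been seen, and the averaging of 500 h replicates 1 and 3 and the filter on recovered signals were added after seeing the data. Gene lists differed between 500 h and 40 h in 4 cases, by the list test of the difference itself. These were the phosphotransferase system (adjusted p = 4.01e-07), acid resistance (adjusted p = 0.00296), the RpoS general stress response (adjusted p = 0.0155) and the tricarboxylic acid cycle (adjusted p = 0.0244), each lower at 500 h. With an estimated correlation all 4 lost the call (adjusted p of 0.202, 0.691, 0.328 and 0.805 in the same order). Over the other settings run, adjusted p reached from 1.06e-08 to 0.883 for the phosphotransferase system, from 6.19e-12 to 0.691 for acid resistance, from 0.00254 to 0.883 for RpoS and from 0.00254 to 0.883 for the tricarboxylic acid cycle. The values of 0.883 belong to names read by the IDs as deposited, and that of 0.691 to the estimated correlation.

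Some named genes had every 40 h array on the opposite side of 0 from every 500 h array, a difference that was not tested beyond the limma fit, where none passed. In log2, 500 h minus 40 h, these were asd (-2.67), bfr (-2.60), elaB (-2.81), focA (-1.58), ftsA (-1.43), leuD (-2.11), manY (-2.59), nuoA (-1.48), ptsG (-1.47), rpoD (-2.13) and yeaQ (-2.39), and aspS (1.46) with the opposite sign. Of the 12, 3 still had opposite signs after centring. Among all 1034 genes with 6 values, 53 had opposite signs as deposited and 32 after centring.

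Calls at 500 h were mostly higher than the control, 86.2% of 2108, but 28.2% of 259 were higher among genes with a value on all 6 arrays, and 0 of 13 with 500 h replicates 1 and 3 averaged and arrays centred. After the loess correction on spot brightness 53.0% of the calls were higher, but centring alone, which uses no brightness, gave 54.8%, so this does not decide whether dim spots with high ratios carry the excess. A control channel shared by 500 h replicates 1 and 3 was tested on the array that does not share it. Of the genes called higher without 500 h replicate 2, 70.85% lay above the median of that array, against 41.2% of the other genes, but this covers 518 of 2035 such genes on 1 array, so the shared channel stays open. No biological explanation was tested.

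RpoS genes lay lower at 500 h than at 40 h as a list with the preset correlation, but not in the test with an estimated one (adjusted p = 0.328). The estimate was -0.00635 and was set to 0, below the preset 0.01, so correlation among the members did not end that call. The test with it also took its degrees of freedom from the 6 arrays. Among spots with recovered signals of at least 100 on centred arrays the call was lost too (17 members, list test adjusted p = 0.338). After the loess correction adjusted p was 0.00254. That test was chosen after its result was seen and uses signals in lowest terms, so it does not decide on a brightness trend. The shared control of 500 h replicates 1 and 3 stays open. List medians relative to the array were 0.58, 0.04 and 0.33 at 40 h. At 500 h they were -0.74 and -0.86 on that pair, against 0.09 on replicate 2. Each array median was taken over the array's own genes, 3985, 1783 and 3967 on 500 h replicates 1 to 3. Those array medians were 1.27, 0.13 and 1.36, so the order of the 500 h arrays depends on the centring. These list medians therefore do not decide. Over the 21 members with all 6 values, 500 h replicate 2 had -0.1445, also relative to the array, close to the lowest 40 h array (-0.07). Leaving out 1 array gave an adjusted p of up to 0.0957, always downward, and lower RpoS activity at 500 h stays open as well, since a separate list of 16 measured RpoS-dependent genes, written before its test, gave a list test p of 0.0662, also downward (0.00258 after loess, 0.269 with both arrays averaged).

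Phosphotransferase genes lay lower at 500 h than at 40 h as a list. The shift kept an adjusted p of at most 9.14e-05 when each array was left out, which argues against 1 array as the whole cause. After the loess correction adjusted p was 5.43e-05. That test was chosen after its result was seen and uses signals in lowest terms, so it does not decide on a brightness trend. Few transcription units carrying the 7 genes were weighed with an estimated correlation, where p was 0.00695, within the bound set beforehand, but that bound left out the adjustment over all lists, which gives 0.202, so this is not excluded. Medians of the list, relative to the array median, were 0.52, -0.55 and 0.76 at 40 h and -2.19, -1.047 and -2.55 at 500 h, so the array without the shared control also lay below the 40 h arrays, which as 1 array excludes nothing. Lower transcription of this system after long limitation is untested and stays open beside these.

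Splits of the 6 arrays into 3 against 3 number 10, too few for a share under 0.05. For single genes, 10 of the 10 splits gave at least as many genes as the real count of 0, and the highest of the other splits was 0. A real count of 0 fixed this outcome in advance, so it decides nothing. At an unadjusted p under 0.05 limma gave 238 genes in the real split and from 15 to 302 in the others. For lists, 2 of the 10 splits gave at least as many as the real 4, and the highest of the others was 5.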

How the results depend on the processing

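The alternatives that average 500 h replicates 1 and 3, select or correct by spot brightness, read names by the IDs as deposited or combine the replicate block with centring were chosen after seeing the data. Except where stated, the cause was not tested.

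Genes changed at 40 h (333) became 199 with arrays centred, 895 with no filter on missing values, 0 with the 40 h arrays alone, 0 with the replicate block, 43 with replicate block and centring, 0 with 500 h replicates 1 and 3 averaged, 36 with averaging and centring, 175 with recovered signals of at least 100 and centring, 148 after loess and 2 by the methods' own test with Benjamini-Hochberg adjustment. At 500 h (2108) the counts were 1189 centred, 259 for genes on all 6 arrays (73 higher and 186 lower), 0 with the replicate block, 272 with replicate block and centring, 0 averaged, 13 averaged and centred, 695 with recovered signals of at least 100 and centring, 219 after loess, and 1302 by the methods' own test at the study's threshold or 0 with adjustment. For the counts of 0, limma gave 511 genes (40 h alone), 525 and 1776 (replicate block at 40 h and 500 h), and 548 and 420 (averaged) at an unadjusted p under 0.05. The difference of the times (0) was 178 by the methods' own test at the study's threshold and 0 under every limma setting. Without 1 replicate the counts ran from 0 to 404 at 40 h, from 0 to 2386 at 500 h, and stayed 0 for the difference, the lowest coming without 500 h replicate 1 or 3. Without 500 h replicate 2, which also leaves 5 arrays, they were 404 and 2322. Whether same-numbered arrays are paired is not stated. Deviations from the group mean of same-numbered arrays correlated across genes with r of -0.0132, -0.183 and -0.158. At 500 h those deviations mostly set replicate 2 against replicates 1 and 3 (r of -0.892 and -0.886). Pairing is thus not excluded.

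Lists past the test numbered 8 at 40 h, 23 at 500 h and 4 for the difference. With an estimated correlation and with names by the IDs as deposited they were 0 in all 3 comparisons. With recovered signals of at least 100 and centring there were 5 and 8 against the control, after loess 8 at 500 h, averaged 10 and averaged and centred 11 at 500 h. Without 1 replicate they ran from 5 to 8, from 9 to 23 and from 2 to 5. Of the 35 list results, 34 kept direction and call with centring, 35 with the replicate block and 16 after loess.

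Among the lists past the test and the called genes of those lists, the reversals were all at 500 h. The ATP synthase list lay at -0.077 after loess with an upward test, and the amino acid biosynthesis list at -0.06404 averaged and -0.06404 averaged and centred, 0.01875 without 500 h replicate 1 and -0.06562 without 500 h replicate 3, each with an upward test, and between -0.60 and 0.02 without 1 replicate. edd turned to -0.11 centred and -0.32 after loess, and after loess cydA turned to -0.53, nuoK to -0.034, ompW to -0.30 and fabH to -0.039. Outside those lists grxA turned from 1.89 to -0.25, ibpA from 1.49 to -0.22 and galR from 2.26 to -0.025 after loess at 500 h. Values not past the test also turned, such as rpoB at 40 h from 0.21 to -0.28 with centring. Of 255 named gene values, 188 kept direction and side of the threshold with centring, 155 after loess and 82 with the replicate block. Whether dim spots with high ratios shape these values was not decided.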

Other observations

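Averaging 500 h replicates 1 and 3 and centring every array, an alternative added after seeing the data, left 36 genes at 40 h and 13 at 500 h past limma's test, 12 of them at both times. Those named here beyond the report were chosen after their values were seen, with values in log2 ± SE. At 40 h bsmA (6.66 ± 0.92), of biofilm stress, cspD (5.48 ± 0.72), a stationary-phase member of the cold shock family, and pspE (2.73 ± 0.54), a thiosulfate sulfurtransferase, rose. Genes that fell include lysP (-3.96 ± 0.73), a lysine transporter, entE (-3.31 ± 0.58), of enterobactin synthesis, queA (-2.79 ± 0.52), of tRNA queuosine, and the ribosomal protein genes rplA (-3.11 ± 0.56), rpmA (-3.15 ± 0.54), rplK (-2.90 ± 0.56) and rplI (-2.76 ± 0.53). At both times exbD, of the energy supply for iron uptake, fell (-2.65 ± 0.52 and -3.56 ± 0.64), as did hflD (-2.98 ± 0.51 and -3.81 ± 0.63).

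A separate list of genes under RpoS, with 16 measured at 40 h, lay above other genes at 40 h (median 1.66 against 0.52 for all genes), and its 22 measured genes at 500 h had a median of 1.15 against 1.27. With 500 h replicates 1 and 3 averaged, its 16 measured genes at 500 h lay above other genes (1.10 against 0.40). The main RpoS list had no call at 40 h (30 measured, adjusted p = 0.238) and lay lower at 500 h (41 measured, 8 rose, 5 fell, 1 and 8 after centring, adjusted p = 0.0230, and 0.117 with an estimated correlation). After loess it had no call at 500 h. Of all 3965 genes tested at 500 h 1818 were higher, and 651 after centring. The 1818 were 401 of the 1780 genes with a value on 500 h replicate 2 and 1417 of the rest. Beside that, lists with no call at 500 h include phosphate starvation (17 measured, 10 rose, 0 fell, 5 and 0 after centring, adjusted p = 0.793), nitrogen limitation (24 measured, 9 rose, 1 fell, 3 and 1 after centring, adjusted p = 0.954), the SOS response and DNA repair (18 measured, 11 rose, 0 fell, 3 and 1 after centring, adjusted p = 0.720) and fatty acid degradation (8 measured, 5 rose, 0 fell, 2 and 0 after centring, adjusted p = 0.219). At 40 h flagella and chemotaxis genes had a median of 1.75 with 2 of 12 past the test, 1 after centring (adjusted p = 0.273).

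Ratios of 500 h replicates 1 and 3, whose control signals coincide, correlated less after the loess correction (r = 0.720 across 3959 genes) than as deposited (r = 0.936). The other pairs of arrays had r from 0.379 to 0.671 as deposited and from 0.292 to 0.507 after it. The highest of these as deposited were across times, 40 h replicate 2 with 500 h replicates 1 and 3 (0.668 and 0.671). With 40 h replicates 1 and 3 that array had 0.469 and 0.503. After loess the values were 0.469 and 0.477 across times and 0.458 and 0.507 within 40 h. The arrays of the former pairs hold the most values, so likeness between arrays did not simply follow time.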
